A study of Caenorhabditis elegans with 2 samples.

How the data were processed

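The data are peak lists from transcription factor ChIP-seq of whole Caenorhabditis elegans larvae of strain OP590, which expresses ZIP-4 with a C-terminal EGFP and FLAG tag. Per the labels, the immunoprecipitation used an antibody to GFP and chromatin was sheared by sonication, and the 2 replicates are separate biological replicates. The antibody field of the labels names zip-4, which is the tagged protein; the description names GFP, and it is followed here. There was 1 group, so no comparison between conditions was possible, and each comparison sets peaks against background regions of the same pooled list, against other genes or against the other replicate.

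The authors deposited 4 lists in narrowPeak format on assembly ce11, per the labels and the accompanying description of the files. Both replicates and their pooled reads each have a list of 30000 regions made as input for the irreproducible discovery rate (IDR) method, which keeps regions whose rank is repeated between replicates. The optimal set of 1290 peaks (1287 distinct intervals) is what the authors kept by IDR. The regions were derived from each replicate's alignments and a control alignment, the same control for both. The aligner, peak caller, its settings, the IDR threshold and the sequencing depth are not given in the sources used here, nor is how reads that map to several places were treated in the peak lists. The length of 30000 is fixed, so most regions of the 3 inputs are weak. Only 1461 pooled regions had a q-value of 0.05 or less, from the −log10 q-value that the authors deposited. The score used for ranking is the deposited signal value, whose scale is not stated; it was used within a list, and beside another list by rank, by correlation and as 1 median ratio between the replicates. The summit is the deposited offset from the start of each interval. The 1290 optimal peaks were the 1290 pooled regions with the highest signal value, the lowest being 79.97, so optimal and pooled lists are one ranking and the background is its weaker part.

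Coordinates are 1-based on ce11. All regions lay within the chromosome lengths of the reference, assembly WBcel235, which is the same assembly. Genes and biotypes came from Ensembl release 115. Regions were called shared where summits lay within 100 bp. Promoters ran from 1000 bp upstream to 200 bp downstream of any protein-coding transcript start. Background regions were the 28526 pooled regions that share no base with an optimal peak. For motifs, 5 background regions per peak were asked for, matched on promoter or not and on GC class of 5 percentage points; 5771 were found and 679 were missing, so matching was incomplete (mean GC 46.1% in peaks and 44.9% in matched regions). Motifs were searched on both strands within 50 bp of the summit, in windows of 101 bp. Non-coding genes were called near within 200 bp.

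Shares have Clopper-Pearson intervals at 95%. Differences between sets were tested with two-sided Fisher's exact tests, with conditional odds ratios and 95% intervals, and adjusted by the Benjamini-Hochberg method within each family (5 annotations, 6 chromosomes, 10 motifs, 26 gene lists, 6 biotypes) at 0.05. Random overlap used 200 draws, correlations 100000 permutations, and matched gene lists 10000 draws. Motifs, gene lists, tests and the alternatives were fixed before the data were examined, apart from those named as added. The 26 lists were ribosomal proteins, heat shock and chaperone genes, respiratory chain, ER stress, bZIP factors, chemoreceptors, C-type lectins, neuropeptides, detoxification, collagens, vacuolar ATPase, autophagy, tRNA synthetases, fasting and fat metabolism, histones, F-box, nuclear hormone receptors, insulin-like peptides, homeobox, insulin signalling and stress resistance, and markers of neurons, germline, body wall muscle, pharynx, hypodermis and intestine. Of the symbols listed, atf-5 and atg-11 had no match in the annotation.

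Genes were named by a rule set before the data were examined. It takes the 20 strongest optimal peaks with a summit within 100 bp in both replicates, named by the nearest promoter gene, then zip-4 and unc-119, then up to 3 members of each list with the strongest peaks, and every bZIP gene with a promoter peak. 1 of the 20 peaks, on IV, is given by position in place of its gene name. Neighbours that share a promoter, and genes named in the closing section, were added after the values were seen.

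Alternatives tried were the 645 optimal peaks with the higher signal value, the 1290 strongest regions of each replicate alone, the 1290 strongest pooled regions, other overlap distances, other promoter widths, other backgrounds and other motif windows. Added after seeing the data were words of 8 bases at summits (those in at least 10 windows), gene lists with and without the degenerate C/EBP word, a matched background for small RNA genes, and motifs and lists without peaks near small RNA genes or without windows that held TTGCGAAA. The scripts were tested on simulated sets. In background regions with nothing planted, 0 of 10 motifs, 0 of 20553 words of 8 bases, 0 of 6 biotypes and 0 of 6 chromosomes were called. A planted palindrome in 5% of windows was called, a planted word of 8 bases had the lowest p, and a list with 40% of its members planted was called in 20 of 20 draws. A planted promoter odds ratio of 3.90 was recovered as 3.90, which checks the arithmetic only. The background sets with nothing planted were random parts of the same list, so they do not test the effect of incomplete matching. No list of regions bound by many factors and no precipitation from untagged worms was analysed here, so binding that any tagged factor would show is not separated from binding by ZIP-4. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.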

Results

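Binding of ZIP-4, a transcription factor of the basic leucine zipper (bZIP) family, was mapped in Caenorhabditis elegans by chromatin immunoprecipitation and sequencing (ChIP-seq). The worms were first-stage (L1) larvae, 6 hours of age, that had been starved after bleaching. They carried a transgene for ZIP-4 fused to EGFP, with unc-119(+) as its rescue marker, and chromatin was precipitated with an antibody to GFP. There was 1 group with 2 biological replicates taken from separate worm preparations, and no group without the tag or in another state. Each replicate had a list of 30000 candidate regions, as had the pooled reads, and the authors' optimal IDR set held 1290 peaks. Not each of these was repeated in both replicates. In the full lists, 1270 had a summit within 100 bp in replicate 1 and 1237 in replicate 2. Sequencing depth was not given in the sources used here, so no value below carries a depth, and intervals cover counting over peaks or genes. Peaks and genes are not biological replicates, and each test over them describes these 2 libraries.

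The strongest peak lay upstream of nipi-3, which encodes a Tribbles-family pseudokinase, and was ranked 1 in the pooled list and in both replicates. It covered X:15607407-15607982 (ce11) in intergenic sequence, with the summit at -298 bp from the start, and had a signal value of 3733 in the pooled list, 2509 in replicate 1 and 1252 in replicate 2. Peaks at genes for other bZIP factors were also among the 20 strongest. The peak of cebp-1, a C/EBP-type factor, at X:1454270-1454743 had a signal value of 2049 and stood at -658 bp. That of xbp-1, the bZIP factor of the unfolded protein response, at III:4193574-4193929 had a signal value of 1319.5 and stood at -57 bp. Other peaks of this set lay upstream of ftt-2 (a 14-3-3 protein), eef-1A.2 (elongation factor 1A), snb-1 (synaptobrevin), rpl-3 (a large-subunit ribosomal protein), dyci-1 (a dynein intermediate chain), Y37B11A.3 and ZC21.10. Shared upstream regions were bound at icd-1 and vps-32.1, at C49G7.10 and irg-2, at F13A7.11 and F13A7.12, at pri-2 and W02D9.2, and at hat-1 and M03C11.3. A further intergenic peak at IV:15646529-15646952 (signal value 1035) lay in the promoters of 2 genes that have sequence names only.

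Of the 20 strongest peaks, 16 had their summit in the promoter of a protein-coding gene. The other 4 were placed by position. The peak at V:14199938-14200491, ranked 2 with a signal value of 3262, was intergenic. The nearest start was that of atfs-1, and the summit stood 3873 bp downstream of it. The peak at V:19529111-19529522 (1294) was intronic. The peak at III:10989387-10989754 (1209) was intronic and lay within 200 bp of an annotated snRNA gene. The peak at I:11964749-11965115 (982) was intergenic and stood at -1816 bp from the start of hsf-1, the heat shock transcription factor. All 20 were among the 20 strongest regions of replicate 1, and 18 were among the 20 strongest of replicate 2, where the lowest rank was 23.

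The first question was how far both replicates gave the same peaks. Of the 1290 peaks, 1139 (88.3%, 95% Clopper-Pearson interval 86.4 to 90.0%) had a summit within 100 bp among the 1290 strongest regions of replicate 1, and 990 (76.7%, 74.3 to 79.0%) among those of replicate 2. Equally many regions drawn at random from the lists gave 4.21% and 4.12%. Both replicates held 876 of the peaks (67.9%) among their 1290 strongest regions, and neither held 37 (2.87%). The optimal set was chosen by the authors from these same replicates, so these shares are not independent of that choice. Without reference to that set, 875 of the 1290 strongest regions of replicate 1 (67.8%, 65.2 to 70.4%) had a partner among the 1290 strongest of replicate 2, against 3.82% at random.

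Sharing depended on rank. Of the regions ranked 1 to 500, 98.4% in replicate 1 and 97% in replicate 2 had a partner summit within 100 bp anywhere in the other list. The shares were 16.1% and 16.2% for ranks 20001 to 30000. Over the 1218 peaks with a region in both replicates, signal values correlated across peaks with a Spearman coefficient of 0.79 and a Pearson coefficient of 0.86 on the log2 scale (permutation p = 1e-05 for each, the smallest that 100000 resamples can give). Without the 2 peaks farthest from the median of replicate 1 they were 0.79 and 0.86. Peaks are not independent replicates. Signal values were 1.89 times higher in replicate 1 at the median peak, on a scale that need not be the same in both lists.

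**Figure D1:**
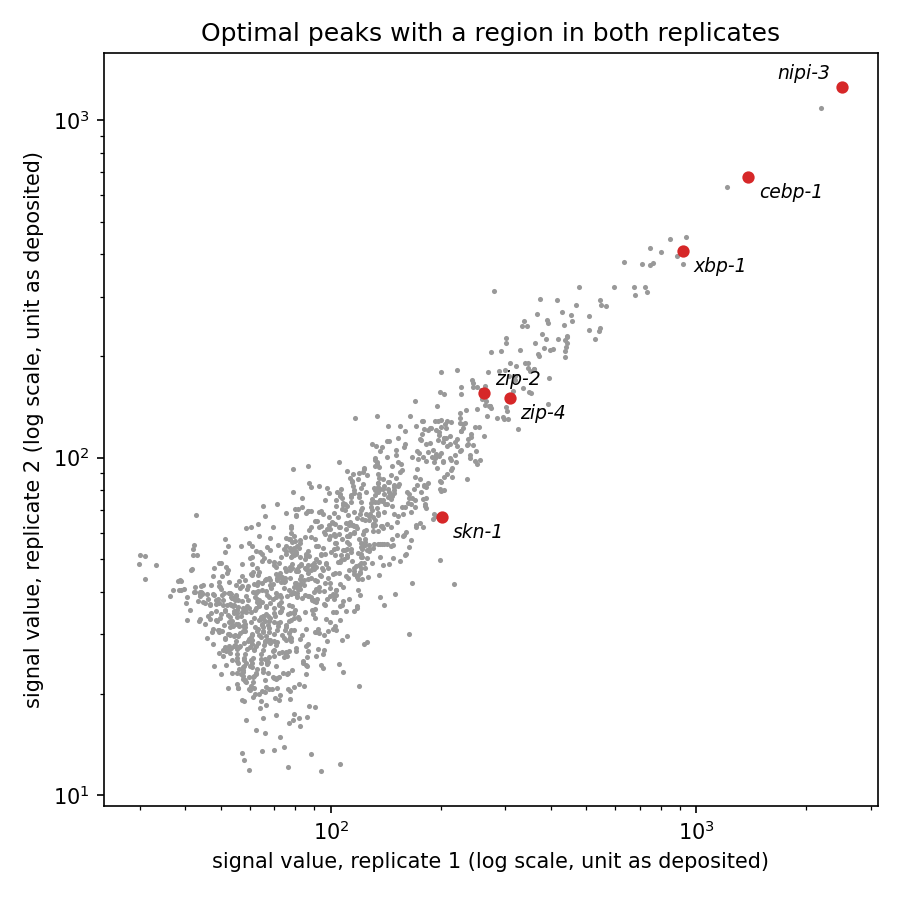
Signal value in replicate 1 (x axis, log scale) against replicate 2 (y axis, log scale) for the 1218 optimal peaks with a summit within 100 bp in both lists, 1 point per peak; the unit is that of the deposited lists. Red points mark the strongest peak at nipi-3 and 5 bZIP genes, and nipi-3 has the highest value in both replicates.

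**Figure D2:**
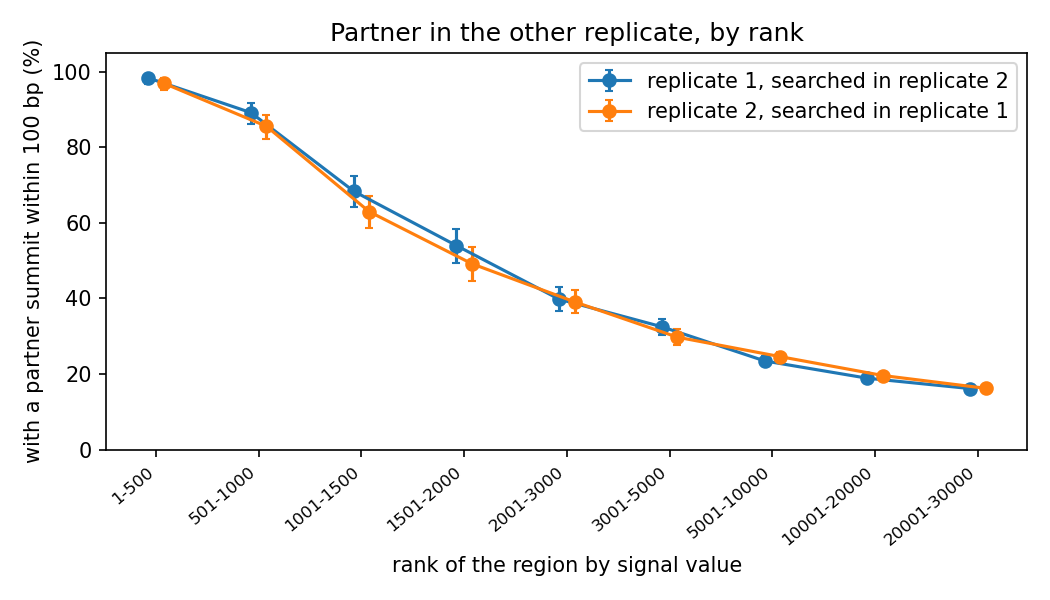
Share of regions with a partner summit within 100 bp in the other replicate (y axis, percent, with 95% Clopper-Pearson intervals) by rank of signal value (x axis). The share is 98.4% and 97% for ranks 1 to 500 and falls to 16.1% and 16.2% for ranks 20001 to 30000.

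ZIP-4 peaks were concentrated just upstream of genes. Summits of 876 of the 1290 peaks (67.9%, 65.3 to 70.5%) lay in a promoter, from 1000 bp upstream to 200 bp downstream of a protein-coding transcript start. The share was 27.8% of the 28526 background regions, which were pooled candidates that touched no peak (Fisher's exact test, two-sided, odds ratio 5.50, 4.87 to 6.21, p = 9.413e-187). Within promoters the median summit stood at -188 bp from the nearest start (quartiles -351 and -82.8 bp), and 93.2% of promoter summits were upstream of it. The promoters belonged to 1141 of 19973 protein-coding genes (5.71%), and 311 summits lay in promoters of 2 or more genes, so a peak cannot always be assigned to 1 gene. A further 199 summits were over 2000 bp from any protein-coding start.

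By annotation, 71.6% of summits were intergenic against 34.1% of background regions, and 3.95% against 1.86% were in 5′ UTRs. Fewer were in coding sequence (2.71% against 32.2%), introns (20.5% against 28.6%) and 3′ UTRs (1.24% against 3.18%). All 5 differences passed Fisher's exact test with Benjamini-Hochberg adjustment, the largest adjusted p being 1.647e-05 for 3′ UTRs. Over chromosomes, the peaks held a larger share than background on III (238 peaks, odds ratio 1.44, 1.24 to 1.66, adjusted exact p = 1.190e-05) and I (212 peaks, 1.24, 1.06 to 1.45, adjusted exact p = 0.0112). Their share was smaller on V (213 peaks, 0.728, 0.624 to 0.847, adjusted exact p = 6.204e-05). II, IV and X did not pass, with adjusted p of 0.262, 0.0549 and 0.165. For chromosome I the call was lost against chromosome length (odds ratio 1.11) and against protein-coding gene starts (1.17), and IV passed as lower against both (0.772 and 0.830). For X, the odds ratio was 0.895 against background regions and 1.45 (adjusted exact p = 1.151e-06) against gene starts.

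**Figure D3:**
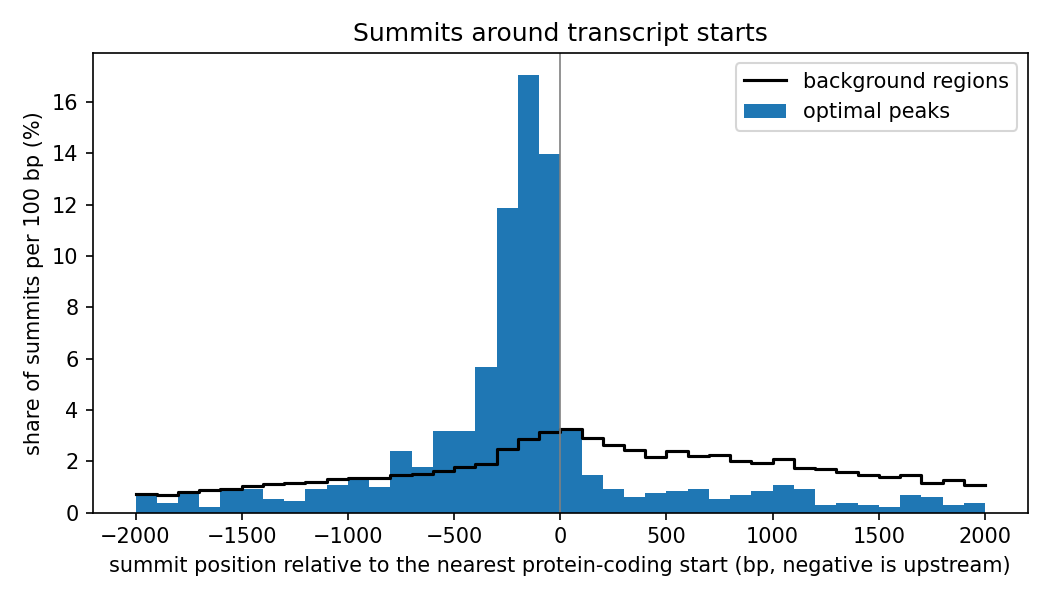
Share of summits per 100 bp (y axis, percent) by position relative to the nearest protein-coding transcript start (x axis, bp, negative upstream). Bars are the optimal peaks and the line is the background regions; promoter summits stand at a median of -188 bp.

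Genes for ribosomal proteins, chaperones, the respiratory chain, the endoplasmic reticulum (ER) stress response and bZIP factors held peaks in their promoters more often than other genes. These were 5 of the 26 gene lists fixed before the data were examined. Of 78 ribosomal protein genes, 38 had a peak (48.7% against 5.54% of other genes, Fisher's exact test, odds ratio 16.2, 10.1 to 26.0, adjusted exact p = 2.140e-25), led by rpl-3 (signal value 1172), rpl-20 (917) and rpl-35 (793). Of 59 heat shock and chaperone genes, 18 had one (odds ratio 7.34, 3.96 to 13.1, adjusted exact p = 2.208e-08). The strongest were at cct-8 (705), a subunit of the cytosolic chaperonin, at hsp-60 (592), the mitochondrial chaperonin, and at hsp-1 (568), an Hsp70. Of 40 respiratory chain genes, 11 had one (6.31, 2.84 to 13.1, adjusted exact p = 4.352e-05), led by cox-5A (650.0), atp-1 (328) and mev-1 (244). Of 20 ER stress genes, 8 had one (11.1, 3.92 to 29.5, adjusted exact p = 3.910e-05). xbp-1 led them, then crt-1 (calreticulin, 311) and hsp-3 (an ER Hsp70, 301), which is also on the chaperone list.

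Of 27 bZIP genes, 7 had a promoter peak (25.9%, odds ratio 5.81, 2.07 to 14.3, adjusted exact p = 0.00234). They were cebp-1, xbp-1, zip-4 (470.1), zip-2 (410.2), skn-1 (266), jun-1 (160.2) and crh-1 (119.9). The transgene also carries zip-4, so the zip-4 peak can reflect its copies, and the list was not tested without zip-4. The peak of zip-2 was at III:833784-833999 and that of skn-1 at IV:5656141-5656536, both in annotated introns. The stronger peak of jun-1 was at II:9117793-9118188, also intronic, and a weaker one had its summit at II:9113023 (rank 984). The peak of crh-1 was at III:11657190-11657585, intergenic. In a split of the peaks made after seeing the data, the bZIP call was lost among peaks without the C/EBP word TTRCNNAA (odds ratio 2.82, adjusted exact p = 0.211), where the other 4 lists passed. Among peaks with it, bZIP factors (14.2) and the respiratory chain (6.94) passed, and ribosomal proteins (3.37), chaperones (2.18) and ER stress (6.90, 2 of 20 genes) did not (adjusted exact p of 0.148, 0.554 and 0.148). The difference itself was not shown for bZIP factors, of whose 9 promoter peaks 5 held the word (odds ratio against other promoter peaks 3.38, 0.720 to 17.2, adjusted exact p = 0.204).

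A further 5 lists held fewer peaks than other genes. Chemoreceptor genes had 5 in 1268 (0.394%, odds ratio 0.0612, 0.0198 to 0.144, adjusted exact p = 2.140e-25), and srh-16 (296), sri-5 (291) and srr-10 (173) had the strongest. None of 240 C-type lectin genes (upper limit of the odds ratio 0.253, adjusted exact p = 1.041e-05) and none of 102 neuropeptide genes (upper limit 0.606, adjusted exact p = 0.0143) had a peak. Detoxification genes had 3 in 185 (0.270, 0.0551 to 0.804, adjusted exact p = 0.0295), namely cyp-33C8 (156), gst-5 (117) and gst-27 (111). The gst-27 peak ranked only 8449 in replicate 2 and lay within 200 bp of a snoRNA gene. Collagen genes had 2 in 156 (0.213, 0.0255 to 0.784, adjusted exact p = 0.0351), namely col-63 (161) and col-38 (128). The calls of collagens, detoxification and neuropeptides were lost with the 645 stronger peaks (adjusted exact p of 0.160, 0.0998 and 0.135) and with the nearest start within 2000 bp (0.203, 0.479 and 0.431). That of collagens was also lost in either replicate alone (0.0951 to 0.165), that of detoxification with narrower promoters (0.166), and that of neuropeptides against random lists matched on upstream intergenic length (adjusted permutation p = 0.0813).

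The remaining 16 lists did not pass, and values in parentheses are their adjusted exact p. These were vacuolar ATPase genes with 4 of 21 (0.0688, led by vha-8, vha-12 and vha-17), autophagy genes with 3 of 19 (0.183, or 0.00106 with the nearest start within 2000 bp; lgg-1, lgg-2 and epg-8), and tRNA synthetases with 4 of 32 (0.199, led by gars-1, ears-2 and rars-1). Fasting and fat metabolism genes had 3 of 24 (0.252, icl-1, cpt-2 and aak-2), histones 6 of 72 (0.441, led by his-37, his-67 and his-68), F-box genes 12 of 322 (0.251, or 0.0211 without replicate 1, as lower; led by fbxc-19, fbxa-150 and fbxa-37) and nuclear hormone receptors 10 of 269 (0.283, led by nhr-47, nhr-56 and nhr-117). Insulin-like peptides had 1 of 39 (0.786, ins-39), homeobox genes 1 of 82 (0.183, ceh-38) and insulin signalling and stress resistance genes 1 of 24 (1, skn-1). Among tissue markers, neuron markers had 2 of 24 (snb-1 and egl-21) and germline markers 2 of 24 (mex-1 and cgh-1), each at 0.730. Body wall muscle (20 genes), pharynx (12), hypodermis (20) and intestine (21) markers had 0, with upper limits of the odds ratio of 3.34, 5.94, 3.34 and 3.17. These intervals leave room for an excess.

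**Figure D4:**
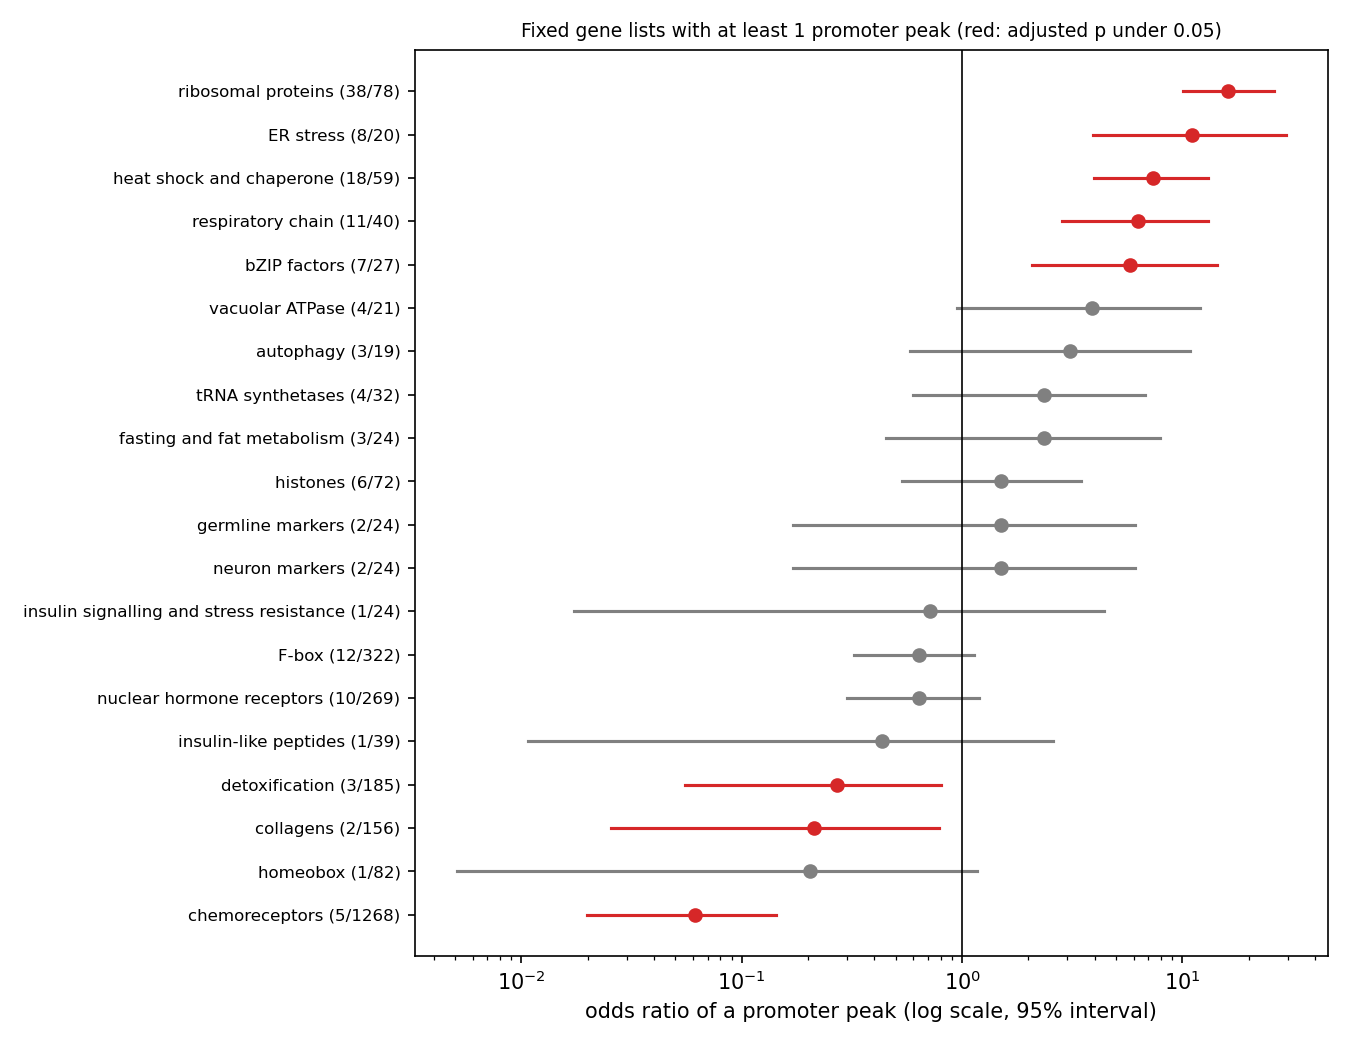
Odds ratio of a promoter peak for members of each gene list against all other protein-coding genes (x axis, log scale) with 95% intervals; the labels give members with a peak and members in all. Red marks an adjusted p under 0.05. The highest is 16.2 for ribosomal protein genes and the lowest drawn is 0.0612 for chemoreceptors; the lists with 0 peaks are not drawn.

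Summits carried C/EBP-type sequence more often than matched background. Within 50 bp of the summit, 342 peaks (26.5%) held the degenerate C/EBP word TTRCNNAA (R is A or G, N any base), against 12% of 5771 background regions matched on promoter share and GC class (Fisher's exact test, odds ratio 2.66, 2.29 to 3.08, adjusted exact p = 5.361e-35 over the 10 motifs). Its palindromic form TTGCGCAA was in 15 peaks (1.16% against 0.173%, odds ratio 6.77, 2.84 to 16.9, adjusted exact p = 1.348e-05). A GA repeat, GAGAGAGA, was in 67 (5.19% against 2.01%, odds ratio 2.67, 1.93 to 3.66, adjusted exact p = 1.294e-08). The other 7 motifs did not pass, with shares in peaks of 5.35% for the CREB core TGACGT, 3.49% for the E-box CACGTG, 3.18% for the GATA word AGATAA, 1.16% for the CRE TGACGTCA, 1.01% for the AP-1 site TGASTCA, 0.620% for TGATGCAA and 0.0775% for TTACGTAA. With the sequence beside the same summits as background, TGACGT, TGACGTCA and CACGTG passed as higher (odds ratios 1.55, 2.32 and 2.35) and AGATAA as lower (0.510). CACGTG also passed within 100 bp (1.49), without replicate 1 (1.495) and against unmatched background (1.54), as did TGACGT (1.38) and, as lower, AGATAA (0.556) against the last, and TGACGTCA passed against shuffled windows (6.88). When the windows that held TTGCGAAA, a single form of the degenerate word, were left out of peaks and background, a choice made after seeing the data, TTRCNNAA was in 11.6% of 1073 peaks and 11% of 5712 regions (odds ratio 1.06, 0.859 to 1.31, adjusted exact p = 0.801). The palindrome and the GA repeat passed there too. Of the 20 strongest peaks, 17 held TTRCNNAA, the exceptions being those at rpl-3, at IV:15646529-15646952 and beside the snRNA gene on III. Of the 55 peaks in ribosomal protein and chaperone promoters, 10.9% held it, against 28.3% of promoter peaks outside these and the respiratory chain list. Of the 13 peaks in respiratory chain promoters, 4 (30.8%) held it.

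The most frequent form of the C/EBP word at summits was TTGCGAAA, which was found in a search chosen after seeing the data. The search covered the 25518 words of 8 bases present in at least 10 windows of peaks and matched background together. TTGCGAAA was in 217 peaks (16.8%, 14.8 to 19%) and in 1.02% of matched background regions (Fisher's exact test, odds ratio 19.6, 14.5 to 26.8, adjusted exact p = 7.645e-107). It was in 16 of the 20 strongest peaks, among them those of nipi-3, cebp-1, ftt-2, xbp-1 and snb-1, and in 38 of the strongest 100. By signal value it fell from 26% of the 323 strongest peaks to 9.01% of the 322 weakest (odds ratio 3.54, 2.21 to 5.81, exact p = 1.297e-08). The forms TTACGAAA (24 peaks, 1.86% against 0.433%, odds ratio 4.36, 2.37 to 7.98) and TTGCGCAA passed too. The median distance of TTGCGAAA from the summit was 12.5 bp over the 217 peaks. Those peaks were chosen for the word within 50 bp, so the distance was bounded. Within 25 bp of the summit, TTGCGAAA was in 6.67% of the 1290 peaks on 1 side and 6.43% on the other. From 25 to 50 bp it was in 2.79% and 2.71%. It was rarer at ribosomal protein, chaperone and respiratory chain promoters (5.88% of 68 peaks) than at other promoter peaks (18.1%), although none of these 3 lists passed alone (adjusted exact p of 0.207, 0.507 and 1), and near tRNA, snRNA and snoRNA genes (2.61% of 153 peaks) than at the other peaks (18.7%).

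**Figure D5:**
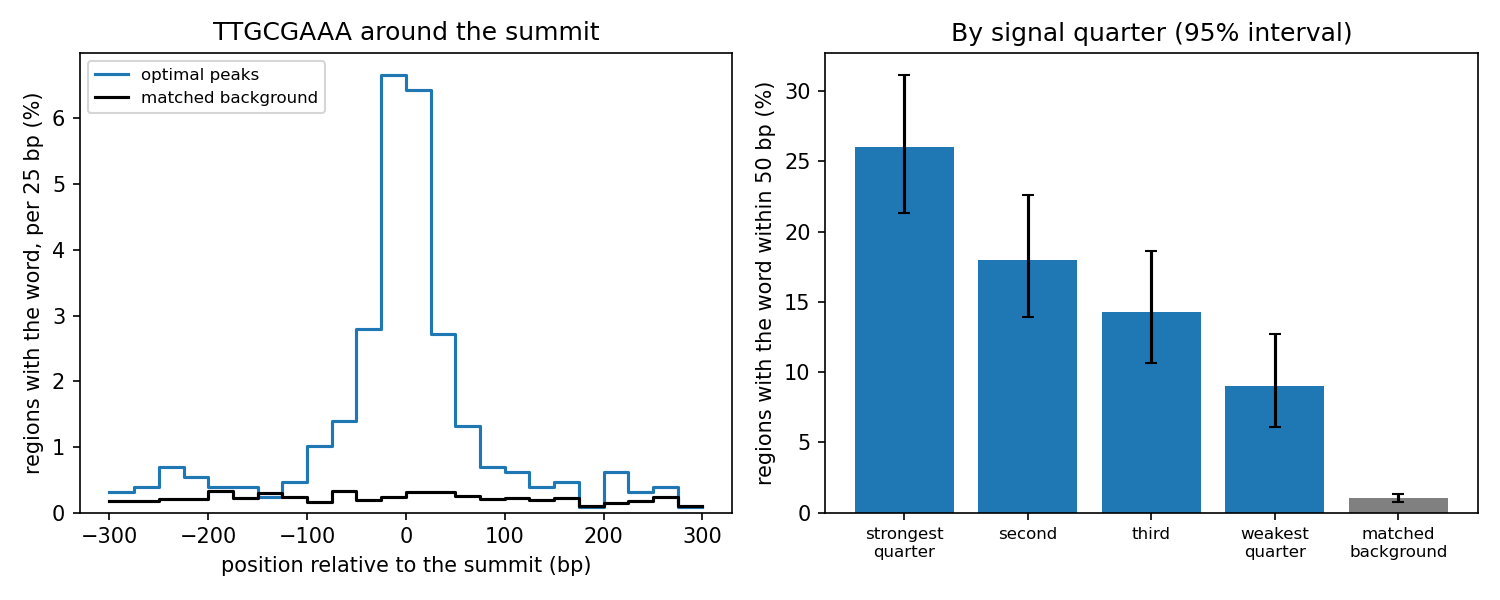
Left, share of regions with TTGCGAAA per 25 bp (y axis, percent) by position relative to the summit (x axis, bp) in optimal peaks and matched background. Right, share with the word within 50 bp of the summit (y axis, percent, 95% Clopper-Pearson intervals) for the peaks in 4 groups of falling signal value, from 26% to 9.01%, and 1.02% in matched background.

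Small RNA genes were close to peaks more often than to background regions. Within 200 bp of the summit, 64 peaks (4.96% against 0.298%) had a snoRNA gene (odds ratio 17.5, 12.4 to 24.6, adjusted exact p = 2.126e-46), 29 (2.25% against 0.0736%) an snRNA gene (31.2, 17.1 to 57.7, adjusted exact p = 1.740e-26) and 61 (4.73% against 0.775%) a tRNA gene (6.36, 4.68 to 8.53, adjusted exact p = 1.699e-25). That background was not matched. With background matched on promoter share and GC class, tRNA, snRNA and snoRNA genes together were near 11.9% of peaks against 1.87% (odds ratio 7.05, 5.43 to 9.19). Of these 153 peaks, 57 also lay in promoters of protein-coding genes, so they overlap in part with the promoter peaks above. The miRNA share was 0.620% against 0.172% of unmatched background (8 peaks, 3.63, 1.48 to 7.74, adjusted exact p = 0.00362). That call was lost against the background matched on promoter share and GC class (odds ratio 2.57, adjusted exact p = 0.0556), a comparison added after seeing the data. piRNA genes were near fewer peaks than background regions (8 peaks, 0.253, 0.108 to 0.502, adjusted exact p = 2.775e-06), and rRNA genes were near none of either. Of the 68 tRNA genes with a peak, 59 (86.8%) had an identical copy elsewhere in the genome, against 75.4% of the 544 others. Gene sequences alone were compared, without their flanks, so whether these peaks can be assigned to 1 copy stays open.

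The transgene brings the zip-4 and unc-119 sequences, so peaks there can reflect its copies as well as the native genes. The zip-4 gene (I:3264111-3266762, minus strand) and its 1000 bp upstream held 2 of the 1290 peaks. The first, at I:3266707-3266859 in intergenic sequence, had its summit at -12 bp from a zip-4 start and signal values of 470.1 in the pooled list (rank 82), 308 in replicate 1 (rank 78) and 149.8 in replicate 2 (rank 98). The second, at I:3266019-3266153 in an intron, had a pooled signal value of 324 (rank 153), and both lay in the promoter of nol-58 too. Candidates were dense around zip-4, with 24 pooled regions in the gene and 20000 bp on each side against a median of 13 in random windows of that size. At unc-119 (III:10902641-10908935, plus strand) there was no peak of the optimal set, and the stronger of 2 pooled candidates had a signal value of 43.4 at rank 6444.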

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

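The gene lists with and without TTRCNNAA, the motifs without TTGCGAAA, the matched background for small RNA genes and the runs without peaks near small RNA genes were chosen after seeing the data. No paired analysis was possible because there is 1 group. Depth was not given in the sources used here, so its limits cannot be stated in reads. The 1290 strongest pooled regions are the optimal peaks themselves, so that alternative moves nothing by construction. The promoter odds ratio and the Spearman correlation kept their direction and their side of the threshold under every alternative run for them.

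The share of optimal peaks found in the 2 replicates depends on what counts as shared. For replicate 1 it was 99.7% with the 645 peaks of higher signal, 90.8% with at least 1 bp of overlap, 85.0% with summits within 50 bp, 97.4% among 2 times as many regions and 98.4% among all regions. For replicate 2 it was 97.5%, 80.2%, 70.5%, 87.2% and 95.9% in the same order, and 79.1% with summits within 200 bp.

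Against chromosome length, 1 chromosome was higher and 2 lower, and against protein-coding gene starts 2 were lower. The odds ratio of X became 1.45 against gene starts; the cause was not tested. With windows 300 to 400 bp beside the summits as background, 6 motifs were higher and 1 lower, and with unmatched background regions 5 were higher and 1 lower; the cause was not tested. Leaving out windows with TTGCGAAA ended the call of TTRCNNAA (odds ratio 1.06). The forms TTACGAAA (odds ratio 4.36) and TTGCGCAA (6.77) were enriched over all peaks as well, but were in only 24 and 15 peaks. No other form passed, the lowest adjusted exact p (Fisher's exact test) being 0.313 for TTACGCAA. Most of the excess of TTRCNNAA was thus that of TTGCGAAA. Of the gene lists, 2 were lower among the 645 stronger peaks, where fewer genes have a peak, and 2 when only the nearest start within 2000 bp was used. Among peaks with TTRCNNAA, 2 lists were higher (bZIP factors and respiratory chain) and 1 lower (chemoreceptors). Among those without it 3 were lower (chemoreceptors, C-type lectins and F-box genes) and bZIP factors lost their call. The F-box call (odds ratio 0.351, adjusted exact p = 0.0425 by Fisher's exact test) was not made over all peaks. At zip-4 there were 5 pooled candidates, 2 optimal peaks, 2 peaks of higher signal and 2 of the strongest 1290, and with 1 replicate left out 2 to 3. At unc-119 there were 2 pooled candidates and 0 under each of these, with a range of 0 to 0. The tally over single lists, chromosomes, biotypes and motifs other than TTRCNNAA had 389 values that kept their side of the threshold. A further 24 lost a call, 15 gained one and 1 reversed, that of X. The 389 include the 1290 strongest pooled regions, which repeat the main result by construction. TTRCNNAA, outside this tally, lost its call in 1 alternative, that without the windows with TTGCGAAA.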

Other observations

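The search over words of 8 bases, the comparisons of that word by gene list, those of the SL2 genes, the separate tests of ribosomal protein and chaperone and of respiratory chain promoters, the tests of identical gene copies and the test of the zip-4 flanks were chosen only after the results they follow up were seen.

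Of 12 F-box promoter peaks, 6 held TTGCGAAA, including that of fbxc-19, against 16.7% of other promoter peaks (odds ratio 4.99, 1.31 to 18.9), which did not pass over the 9 lists compared (adjusted exact p = 0.0775). For the degenerate C/EBP word it did not pass either (adjusted exact p = 0.151). Of the bZIP promoter peaks, 4 of 9 held TTGCGAAA (adjusted exact p = 0.207), and of those of ER stress genes 1 of 8 (adjusted exact p = 1). Outside promoters 16.2% of peaks held the word and in promoters 17.1% (odds ratio 1.07, 0.774 to 1.49). Of 232 occurrences, 75% were preceded by A and 81.5% followed by T.

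Of the 482 words more frequent at summits at an adjusted p under 0.05, 3 held the C/EBP pattern in full; others, such as ATTGCGAA, share part of TTGCGAAA. GCGCCAGC was in 4.73% of peaks against 0.503% of background, AAACGCGC in 5.12% against 0.728% and GACGCAGA in 7.75% against 1.94%. None of these was compared with shuffled windows, and matching on GC was incomplete, so base composition stays open for them. A further 18 words were less frequent. Of 18 SL2 spliced leader genes (sls-2), 8 had a peak within 200 bp, against 13 of 99 snRNA genes other than sls-1 and sls-2 (Fisher's exact test, odds ratio 5.19, 1.49 to 17.95). The 12 SL1 genes (sls-1) had no candidate region within that distance in any list, so no peak could be found there.

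A hypothesis for the peaks at ribosomal protein, chaperone and respiratory chain promoters is that ZIP-4 may be recruited there through the C/EBP word. Over these 68 peaks the odds ratio of the degenerate word against other promoter peaks was 0.436 (0.195 to 0.880), and for the 55 ribosomal protein and chaperone peaks it was lower than 1 too (0.310, 0.107 to 0.738; 10.9% against 12.3% of matched background in promoters), which argues against it as the whole cause there, and the respiratory chain stays open (1.12, 0.250 to 4.07, 13 peaks; the difference between the parts was not tested). TTGCGAAA was rarer in the 68 than in other promoter peaks (odds ratio 0.284, 0.0738 to 0.781) yet more frequent than in that background (5.88% against 1.13%, 5.44, 1.38 to 15.7), so it may account for some of them and not for most. GC content of the promoters was argued against, since the odds ratio over 10 GC classes was 10.3 (7.53 to 14) and 10.6 without classes. Signal that any precipitation gives at highly transcribed, open promoters, indirect recruitment and recruitment through other words stay open, and no other biological explanation was tested.

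Peaks near tRNA, snRNA and snoRNA genes, 153 in all, may reflect position in GC-rich promoters, but the odds ratio against background matched on both was 7.05 (5.43 to 9.19). Recruitment through the C/EBP word is argued against as the whole cause, with odds ratios of 0.335 (0.189 to 0.561) for the degenerate C/EBP word and 0.117 (0.0310 to 0.310) for TTGCGAAA, these peaks against the others; against matched background that of TTGCGAAA was 2.60 (0.677 to 7.15). Reads shared between identical copies are a possible explanation at tRNA genes, where genes with a peak had an identical copy more often (odds ratio 2.14, 1.02 to 5.04, exact p = 0.0469). That p was not adjusted for the tests of the other gene types, and gene sequences were compared without their flanks, so this is weak evidence. Of the 21 snRNA genes with a peak, 7 (33.3%) had an identical copy, against 34.3% of the others (odds ratio 0.960, 0.300 to 2.81). Most snRNA genes with a peak thus had no identical copy, and the interval is too wide to decide on a part. Of the snoRNA genes 0 had an identical copy, which argues against reads shared between identical copies there. Copies that are nearly identical were not compared, so reads shared between those stay open at both gene types. Open chromatin at strongly transcribed genes and recruitment through other words stay open, and no other biological explanation was tested.

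At zip-4, extra copies of the transgene may raise the signal of the locus. The strongest zip-4 signal was at least 6.57 times the median of the candidates in the 20000 bp flanks in both replicates. This excludes nothing, since an insert shorter than the flanks would itself raise that ratio and its extent is not given in the sources used here, so extra copies stay open. The gene and flanks held 24 pooled candidates against a median of 13 in random windows, a number reached by 2.20% of them. Binding of ZIP-4 to its own gene through the C/EBP word is a further candidate explanation. Of the 2 summits, only the weaker one, in the intron (rank 153), held the degenerate C/EBP word, and also TTGCGAAA. The stronger one (rank 82), at -12 bp from a zip-4 start, held neither. At the matched background share of the degenerate word, chance alone would give at least 1 of 2 in 22.5% of cases, so this is weak evidence. TTGCGAAA was in 1.02% of matched background, but it was chosen on these same peaks and its chance was not computed.

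A hypothesis is that TTGCGAAA may mark sites bound by ZIP-4 or a partner. That it arose from choosing a word on the same peaks was tested by picking the word with the lowest p on chromosomes I, II and III, which was TTGCGAAA again. On IV, V and X, whose peaks had entered the first search, its odds ratio was 26.96 (17.4 to 43.1), and against dinucleotide-shuffled copies of the same windows it was 16.3 (12.4 to 21.5). Both argue against chance choice and base composition. Direct binding was not tested and stays open.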
